A study of Mus musculus with 150 samples.

How the data were processed

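The series holds 150 samples of mouse lung cells. The labels give 3 bulk wild-type libraries, 3 bulk p53 knockout libraries, 73 wild-type and 69 knockout single-cell samples, and 1 negative and 1 positive off-chip control of the knockout chip. Groups were taken from the genotype and title labels. For 2 of the knockout cell samples no column was matched, and they are not analysed here. Per the labels' protocols, bulk cells came from mice aged 8 to 12 weeks, and were made into libraries with a low-input SMARTer kit and sequenced as single reads of 75 nucleotides. The bulk titles name day 30, while the protocol names 70 days after tamoxifen, the drug that switches on the Cre recombinase. The genotype label reads as a full knockout and the bulk protocol names floxed alleles. The single-cell labels of both genotypes give tamoxifen at 250 mg/kg. Whether those cells carried a full or an induced deletion is not clear from the labels. Per the labels' protocols, single cells were captured on C1 chips with 92 ERCC spike-in RNAs. Whether the captured cells were fresh or cultured is not clear from the labels.

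The bulk table holds FPKM values made by the authors, with TopHat, Bowtie2 and Cufflinks on mm10, per the submitters' processing notes. Cufflinks' normalization setting is not given in the sources used here. The deposited table of 24341 rows has 0.01 as its lowest FPKM value and 20 entries marked in place of a value (13 as low data and 7 as failed), in 12 genes. Genes with a marked entry were left out, among them Scgb1a1, Sftpc, Sftpa1, Cyp2f2 and Lyz2; 9 of those left out were otherwise expressed. The column of wild-type replicate 6 lacks a name prefix that the other 5 columns share, and a batch of 1 library cannot be tested. The single-cell tables hold TPM values made by the authors with RSEM 1.2.20 and Bowtie 1.1.1 on GRCm38, per the submitters' processing notes, in a separate table for each genotype. FPKM and TPM carry no read counts, so no count test was used.

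Bulk values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (eBayes with trend and robust), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes needed an FPKM of at least 1 in at least 3 of 6 libraries. A fold change on this scale understates the change of low genes. Nothing in the labels says that libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. The 26 gene lists were fixed before the data were examined and were tested with camera at an inter-gene correlation of 0.01, then with an estimated correlation and with fry. Under both of these alternatives 0 lists passed. Lists with fewer than 5 tested members were not given to camera, and the camera lists without a result in the report had adjusted p-values above 0.05.

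Single cells with a debris or valve remark were left out (1 wild type and 3 labelled knockout), as were those with fewer than 1000 genes at a TPM of at least 1 (6 and 3). Differences are of mean log2(TPM + 1), cells labelled knockout minus wild type, with no test, since each genotype is 1 sample. Genes were counted by size at a difference of at least 2 with detection in at least 30% of the cells of the higher genotype; ERCC rows were not counted as genes. List medians used members detected in at least 10% of cells of either genotype and were set against 10000 random lists of the same size matched on mean expression. The random lists were drawn gene by gene and hold no correlation between genes. For lists whose genes vary together, extreme percentiles can therefore overstate how unusual a list is. Shares have exact binomial intervals at 95% and differences of shares have Newcombe intervals; these cover counting error only. The share that a count of 0 allows is given as 3 cells of the total. Cells were clustered with scanpy 1.11.5 on 1000 variable genes present in at least 5 cells, centred within genotype, with 10 principal components, 15 neighbours and Leiden resolution 1. Clusters were named from markers fixed before the data were examined. The labels' protocol states that wells with doublets or debris were removed by inspection, and no doublet caller was run. Kept cells had medians of 3130.5 (wild type) and 3580 (labelled knockout) detected genes, and medians of 13.2% and 6.28% of TPM in ERCC spike-ins.

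Named genes followed a rule fixed before the data were examined. In bulk it takes Trp53, the 8 higher and 8 lower genes of largest fold change past the threshold with a mean FPKM of at least 5 and no overlap, places left open being filled by the smallest unadjusted p, and up to 4 members of each list. In single cells it takes Trp53, the 8 higher and 8 lower genes of largest difference by size, up to 3 members of each list, and the genes named from bulk. The result of 1 gene among the largest differences by size is not reported here. Other genes named, such as Foxj1, Enkur and Odf3b in bulk, Mdm2 in single cells and the leading genes of the clusters, were chosen after their values were seen. Coordinates are from GENCODE release M21 on mm10.

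The bulk test was checked on simulated data for this comparison over 11816 genes: 65.0% of genes changed by 1 on the log2 scale and 88.5% of those changed by 2 were recovered, with 8 false calls. Its noise was drawn independently for each gene, with no correlation between genes and no outlying library. These shares therefore need not hold for the real libraries. The size rule was tested on wild-type cells split at random over 31267 rows, where it recovered 70.5% of 200 changed genes and counted 2 others. The simulated changes were large and placed only in widely detected genes. All these cells came from the same chip, so the check holds no difference between chips and gives no error rate for the real comparison. Alternatives tried for bulk were pseudocounts of 0.1 and 5, other filters, median and quantile scaling, another variance model, library weights and leaving out each library. For single cells they were other cell filters, single classes, pseudocounts of 0.1 and 10, ratios of mean TPM, centring of each cell and other detection limits. Added after seeing the data were TPM rescaled without spike-ins, the alveolar-type-2-like clusters alone, clustering without the genes that differed by size, and the comparison of Trp53 with genes in a like share of cells at any TPM above 0. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.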

Results

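Gene expression was measured in mouse lung epithelial cells, labelled as wild type or p53 knockout, by bulk RNA sequencing of sorted cells and by single-cell RNA sequencing on Fluidigm C1 chips, which capture single cells in microfluidic wells. The design text puts the question as the behaviour of progenitor cells with and without p53, the transcription factor encoded by Trp53. The bulk set held 3 wild-type libraries (replicates 1, 5 and 6) and 3 knockout libraries (replicates 7, 8 and 10). For these, cells carrying a green fluorescent label switched on in the Scgb1a1 lineage, positive for EpCAM and negative for CD31, CD34 and CD45, were sorted; Scgb1a1 is the secretory protein of airway club cells. Of the single cells, 66 wild-type cells and 61 cells labelled knockout were kept. Summed FPKM ranged from 437710 in wild-type replicate 1 to 678870 in wild-type replicate 6, and 11744 to 11933 genes had an FPKM of at least 1 per library. The number of reads per library is unknown from FPKM and TPM values.

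In the bulk libraries Trp53 was lower in all 3 knockout libraries than in any wild-type library. Its level was 20.2 ± 3.09 FPKM in wild type and 8.73 ± 1.21 FPKM in knockout (SD, n = 3 each), a ratio of 2.31. On the log2(FPKM + 1) scale the fold change was -1.12 with a standard error of 0.149. The limma adjusted p was 0.144, so Trp53 did not pass the threshold over 11957 tested genes, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. Trp53 lies on chromosome 11 from 69580359 to 69591873 (mm10), and its whole-gene FPKM also counts exons outside the deleted part.

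Of 33 tested members of the p53 target list, genes that p53 is known to activate, 22 had a negative fold change, with a median log2 fold change of -0.15, which was -0.24 without wild-type replicate 1 and -0.09 without knockout replicate 10. With adjustment over the list alone 8 members fell, and 0 passed over all genes. These were Cdkn1a, which encodes the cell cycle inhibitor p21; Bbc3, which encodes the pro-apoptotic protein Puma; Ccng1, Sesn2, Phlda3, Gdf15, 9030617O03Rik and Psrc1. Cdkn1a was at 47.2 ± 14.6 FPKM in wild type and 19.7 ± 1.66 FPKM in knockout, and Bbc3 at 11.2 ± 1.25 FPKM and 4.85 ± 0.471 FPKM (SD, n = 3 each). Phlda3 was at 16.6 ± 4.41 FPKM and 6.74 ± 1.60 FPKM. Psrc1 was at 6.35 ± 3.08 FPKM and 0.420 ± 0.417 FPKM, 1 of its knockout libraries being listed at the lowest value, 0.01. The list was past the set test (limma camera, adjusted p = 5.17e-04), which was lost with an estimated correlation (adjusted p = 0.40 with an estimated correlation).

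**Figure D1:**
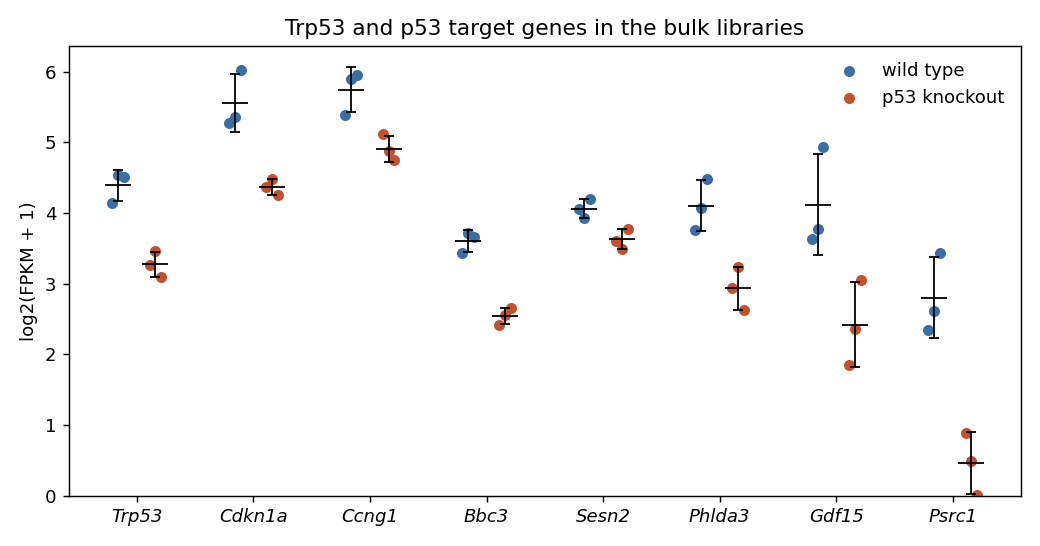
Expression of Trp53 and 7 p53 target genes in each bulk library, as log2(FPKM + 1); points are libraries, horizontal marks the mean and bars the SD of 3 libraries per genotype. For each gene the 3 knockout libraries lie below the 3 wild-type libraries, as for Bbc3 with 11.2 FPKM in wild type and 4.85 FPKM in knockout. The 7 targets were taken from the 8 that fell adjusted over the list alone, so their separation follows from that choice. Of the 33 tested targets 11 had a positive fold change.

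Genes of ciliated cells, the motile cells of the airway lining, had positive fold changes across the list, without a member that passed by itself. All 46 tested members of the list had a positive fold change, with a median log2 fold change of 1.24. Foxj1, the transcription factor that drives motile cilium formation, is among them, as are the list's smallest p-values, those of Fam183b (27.2 ± 20.2 FPKM in wild type, 86.2 ± 27.8 FPKM in knockout; SD, n = 3 each) and Myb (3.28 ± 1.78 FPKM and 7.22 ± 0.769 FPKM). The list was past camera (adjusted p = 3.30e-18), while 0 members passed over all genes or adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.668 with an estimated correlation). Wild-type replicate 1 overlapped the knockout libraries: its mean level over the list was 3.73 on the log2 scale, against 2.36 and 2.21 in the other wild-type libraries and 3.56 to 4.23 in knockout.

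Genes of alveolar type 2 cells, the surfactant-making cells of the alveoli, and of immune cells had negative fold changes across their lists. All 17 tested alveolar type 2 genes had a negative fold change, with a median log2 fold change of -0.98 (camera adjusted p = 1.28e-06, and adjusted p = 0.668 with an estimated correlation); 0 members passed adjusted over the list alone. Lamp3, a lamellar body protein, was at 382 ± 268 FPKM in wild type and 154 ± 18.7 FPKM in knockout (SD, n = 3 each). All 18 immune genes had a negative fold change, with a median of -0.88, and 12 fell adjusted over the list alone (camera adjusted p = 5.07e-12, and adjusted p = 0.387 with an estimated correlation). Cd52 was at 14.0 ± 3.48 FPKM and 5.79 ± 1.15 FPKM, and Coro1a at 9.15 ± 0.338 FPKM and 4.11 ± 1.28 FPKM. CD45, the product of Ptprc, was among the proteins excluded by the sort. All 8 tested genes of MHC class II, the antigen presenting proteins that alveolar type 2 and immune cells both carry, had a negative fold change, and 7 fell adjusted over the list alone. Their median was -1.06 (camera adjusted p = 1.86e-06, and adjusted p = 0.668 with an estimated correlation), and H2-Aa was at 367 ± 187 FPKM and 146 ± 38.1 FPKM. Wild-type replicate 1 had the highest mean level of both the alveolar type 2 list (9.60 on the log2 scale, against 8.45 and 8.47 in the other wild-type libraries and 7.92 to 8.18 in knockout) and the MHC class II list (6.31, against 5.17 and 5.66, and 4.36 to 5.06 in knockout). Without this library the alveolar type 2 median was -0.46, still past camera. Of 25 inflammation and NF-kB genes, 21 had a negative fold change and 4 fell adjusted over the list alone, among them Nfkbiz, Il1rn and Cxcl2 (camera adjusted p = 1.46e-05, and adjusted p = 0.387 with an estimated correlation).

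**Figure D2:**
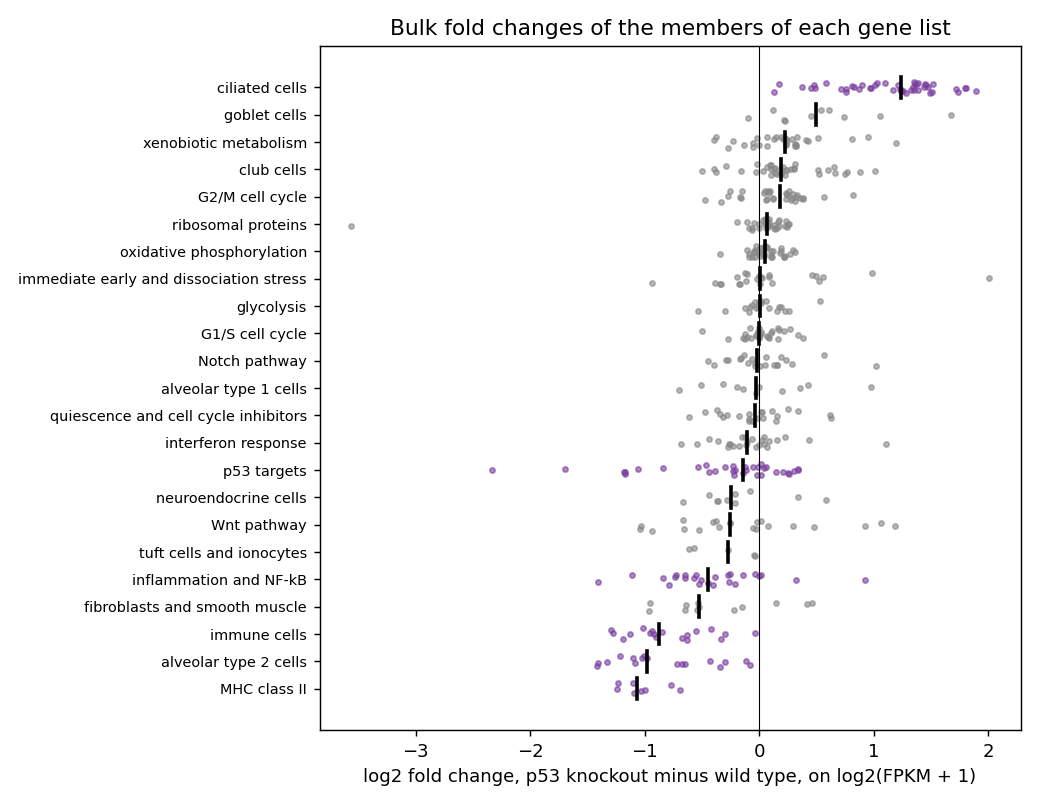
Log2 fold change (knockout minus wild type, on log2(FPKM + 1)) of the tested members of each gene list with at least 5 tested members in bulk; points are genes, black bars the list medians and purple marks the 6 lists past camera. The ciliated list has the highest median, 1.24, and the MHC class II list the lowest, -1.06.

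The club cell and cell cycle lists did not pass the set test. Of 37 club cell genes, 30 had a positive fold change, with a median log2 fold change of 0.19 (camera adjusted p = 0.307). The direction rested on wild-type replicate 1, whose mean level over the club cell genes was 7.77 on the log2 scale against 8.66 to 9.08 in the other 5 libraries. Without it the list was lower in knockout (adjusted p = 0.0132), and it was higher without wild-type replicate 5 (adjusted p = 0.00669) or replicate 6 (adjusted p = 0.0432); over all 6 libraries the adjusted p was 0.913 with an estimated correlation. Scgb1a1 itself could not be tested, because the table marks it as not quantified in all 6 libraries. The G1/S list had a median of 0.00 over 30 genes (adjusted p = 0.692) and the G2/M list a median of 0.18 over 32 genes, 25 of them with a positive fold change (adjusted p = 0.225). The G2/M median was 0.26 without knockout replicate 8, past camera (adjusted p = 0.0167), but 0.04 without wild-type replicate 1 (adjusted p = 0.817) and 0.07 without knockout replicate 10 (adjusted p = 0.739). Over all 6 libraries the G2/M adjusted p was 0.894 with an estimated correlation. Kpna2, a nuclear import carrier, was at 22.8 ± 3.11 FPKM in wild type and 50.1 ± 1.78 FPKM in knockout (SD, n = 3 each), with a limma adjusted p of 0.0890.

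Among the other lists, 4 endothelial genes could be tested, a type gated out through CD31 and CD34, and Egfl7 and Esam fell adjusted over the list alone. Sparc and Vim, of the fibroblast and smooth muscle list, fell adjusted over the list alone (camera adjusted p = 0.0671 for the list); without wild-type replicate 1 the median of that list moved from -0.53 to 0.01, and without wild-type replicate 6 it was -0.85, past camera (adjusted p = 5.48e-06). Over all 6 libraries its adjusted p was 0.875 with an estimated correlation. Of the Wnt pathway genes 4 changed adjusted over the list alone, 1 higher and 3 lower (camera adjusted p = 0.115 for the list). Of the immediate early and stress genes 5 changed adjusted over the list alone, 3 higher and 2 lower (camera adjusted p = 0.712 for the list). Goblet cell genes had a median log2 fold change of 0.50, 9 of 10 being positive (camera adjusted p = 0.307); their mean level was 3.45 in wild-type replicate 1 and 5.17 to 6.30 in the other 5 libraries. Without that library the goblet median turned to -0.24, without knockout replicate 8 it was 0.12, and without wild-type replicate 5 it was 0.92, past camera (adjusted p = 0.0432). Over all 6 libraries the goblet adjusted p was 0.913 with an estimated correlation.

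Over single genes, 1 of 11957 passed the threshold. Mir6374, annotated as a microRNA of 107 nucleotides on chromosome 6 from 83400996 to 83401102 (GENCODE, mm10), lies within an intron of Tet3 on the same strand. It was at 20.4 ± 5.98 FPKM in wild type (SD, n = 3) and listed at 0.01 in all 3 knockout libraries (limma adjusted p = 0.00246). Values for so short a gene inside another are uncertain. At an unadjusted p under 0.05 there were 842 higher and 724 lower genes, and 2304 genes (19.3%) did not overlap between genotypes, against 10% by chance.

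The genes that filled the named places after Mir6374 did not pass. On the higher side, Edn2, which encodes an endothelin peptide, was at 2.40 ± 0.827 FPKM in wild type and 21.4 ± 9.43 FPKM in knockout (SD, n = 3 each; limma adjusted p = 0.110). F3, which encodes tissue factor, was at 55.1 ± 9.45 FPKM and 144 ± 25.2 FPKM, and Ctgf, a matricellular growth factor, at 8.21 ± 4.87 FPKM and 33.4 ± 6.39 FPKM. 2300005B03Rik, Hspa1b, Nr1d2 and Coq10b filled the other higher places, beside Kpna2. On the lower side, Cry1 (16.1 ± 2.75 FPKM and 6.14 ± 0.382 FPKM) and Npas2 (22.5 ± 3.45 FPKM and 10.3 ± 0.973 FPKM), genes of the circadian clock, stood beside Fbxo32, Mir6363, H1f0, Bbc3 and Trp53. Their limma adjusted p-values were 0.0890 for Cry1 and 0.144 for Npas2. The number of calls rested on wild-type replicate 1: without it, 408 genes passed (337 higher and 71 lower), with Enkur, Odf3b and Foxj1 among the smallest p-values and Trp53 past the threshold. With library weights that limma estimated from the spread of these same libraries, 913 genes passed, 654 higher and 259 lower.

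In the single cells, Trp53 was detected in more of the cells labelled knockout than of the wild-type cells, against the labels. It was detected at a TPM of at least 1 in 4 of 66 wild-type cells (6.06%, exact 95% interval 1.68% to 14.8%) and in 16 of 61 cells labelled knockout (26.2%, 15.8% to 39.1%), a difference of 20.2 percentage points. With any TPM above 0 counted, it was detected in 12 of 66 and 19 of 61 cells, a difference of 12.97 percentage points with an interval from -2.02 to 27.5. Mean TPM was 13.2 in wild type and 37.6 in cells labelled knockout. The gap came from alveolar-type-2-like cells (0 in wild type and 59.3 labelled knockout), while club-like cells were at 22.4 and 22.5. It rested on few cells: in cluster 1 mean TPM was 0 and 94.7, with detection in 0 of 14 and 2 of 13 cells. In cluster 3 it was 0 and 20.9, with detection in 0 of 13 and 3 of 12 cells. The wild-type cells of cluster 1 had a median of only 1504.5 detected genes. Within the club-like clusters mean TPM of wild-type cells and cells labelled knockout was 3.42 and 32.9 in cluster 2 (2 and 7 cells), 31.6 and 25.1 in cluster 4, and 17.8 and 10.15 in cluster 5. Detection was in 1 of 2 and 2 of 7 cells of cluster 2, 2 of 15 and 5 of 19 of cluster 4, and 1 of 22 and 4 of 10 of cluster 5. TPM summed over the whole gene does not separate the deleted exons from the rest. Each genotype was 1 chip with no animal named, so no test was possible and intervals cover counting error only. The chips came as separately normalized tables, and every direction below is between cells by these labels.

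The cells were of an airway and an alveolar kind. Unsupervised clustering gave 5 clusters, of which 3 were club-like (clusters 2, 4 and 5) and 2 were alveolar-type-2-like (clusters 1 and 3). Clusters 2 and 4 carried Scgb3a1, Bpifa1 and Reg3g, secreted proteins of the airway surface, while cluster 5 was led by Clic3, Prdx6 and Cyp2f2, the last a club cell cytochrome. Cluster 2 also held Sftpc, the surfactant protein C transcript, at a mean of 16.1 ± 0.72 on the log2(TPM + 1) scale (SD over 9 cells), beside 18.1 ± 0.25 for Scgb1a1. The alveolar type 2 genes Lamp3 and Lyz2 were each in 100% of its cells, at means of 5.64 and 12.27, against 4.68 and 10.95 in cluster 1. Its median of 4400 detected genes was the highest of the 5 clusters. Cluster 2 is counted as club-like in all values given for club-like cells. Among the alveolar-type-2-like cells, 10 of 27 wild-type cells and 10 of 25 labelled knockout had more Scgb1a1 than Sftpc. In cluster 1 the wild-type cells had a median of 1504.5 detected genes and 43.65% of TPM in spike-ins, against 2943 genes and 16.4% in cells labelled knockout. Doublets were not called. Club-like cells made up 39 of 66 wild-type cells (59.1%, 46.3% to 71.05%) and 36 of 61 cells labelled knockout (59.02%, 45.7% to 71.5%). Centring within genotype can even out such shares. Without it they were 56.06% and 63.93%, and without the genes that differed by size they were 65.15% and 59.02%. A like composition of the chips was therefore not shown. Most wild-type club-like cells were in cluster 5 (22 cells) and most of those labelled knockout in cluster 4 (19 cells). The genes leading these clusters differed between the chips, so cluster sizes are not compared. Foxj1 was detected in 1 of 66 wild-type cells and in 0 of 61 cells labelled knockout, which allows up to 4.92% of cells with this transcript detected and sets no limit on the share of ciliated cells.

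**Figure D3:**
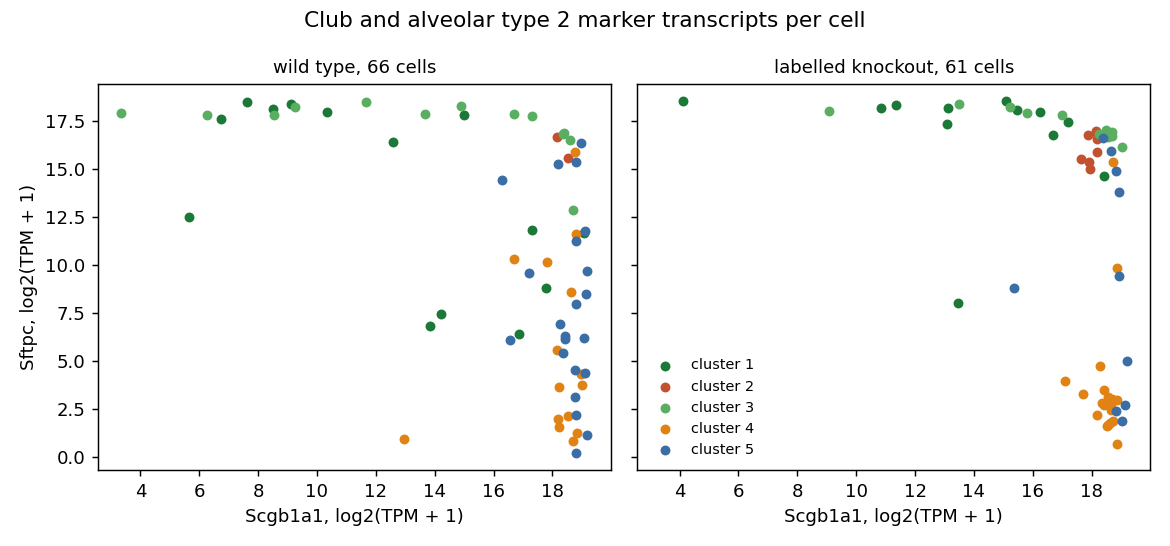
Scgb1a1 (horizontal) against Sftpc (vertical) in each kept cell, as log2(TPM + 1), with 66 wild-type cells on the left and 61 cells labelled knockout on the right; colours are the 5 clusters. Cells with both transcripts at high levels lie in the upper right of both panels.

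By size, 56 genes differed by at least 2 on the log2(TPM + 1) scale, 53 higher and 3 lower in cells labelled knockout. The count was 6 with a pseudocount of 10 and 314 with a pseudocount of 0.1. With each cell centred 5 genes were higher and 7 lower, and by ratio of mean TPM 76 were higher and 10 lower, of which 9 were shared with the 56 in the same direction. Among the largest higher genes were Reg3g, an antimicrobial lectin, with means of 3.63 ± 5.46 and 7.36 ± 6.31 (SD over 66 and 61 cells, here and below), Bpifa1 (4.37 ± 5.57 and 8.00 ± 6.59), Bpifb1, Chil1, Selk, Clu and Ssr3. For Clu the direction turned by mean TPM, which was 1151 in wild type and 661 in cells labelled knockout. Reg3g was detected in 37.9% of wild-type cells and 65.6% of cells labelled knockout, and Selk in 53.03% and 95.1%. Tff2 and Agr2, goblet cell genes, were higher by 2.67 and 2.54. Tff2, Agr2, Reg3g, Bpifa1 and Bpifb1 were leading genes of cluster 2 (2 wild-type cells and 7 labelled knockout). All but Agr2 also led cluster 4 (15 and 19). Reg3g was detected in 97.1% of the cells of cluster 4 and 21.9% of those of cluster 5. The mix of clusters was not separated from the level per cell for these genes. The 3 lower genes were Rps2-ps6 and Gm6576, processed pseudogenes, and Erdr1. Rps2-ps6 was detected in 77.3% and 24.6% of cells while Rps2, a ribosomal protein gene, was in 90.9% and 98.4%; reads shared between near-identical copies make these uncertain. More genes were detected in cells labelled knockout, with medians of 3580 against 3130.5 per cell, and the median difference over 9486 genes was 0.24. Centring each cell on its widely detected genes lowered every difference alike, to a median of -0.57, so lists are given beside random lists matched on expression. These random lists hold no correlation between genes, so extreme percentiles below can overstate how unusual a list is.

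The p53 target genes stood low against matched genes. Their median difference over 28 members was 0.01, against 0.20 for random lists, at percentile 0.4 of 10000 lists. The median stood at percentile 2.6 with remarked wells included, 1.7 with no minimum of genes and at most 0.5 under the other settings over all cells. In club-like cells it was -0.20 over 32 members, at percentile 0.0 after rounding, 20 of them being lower. In alveolar-type-2-like cells it was 0.23 over 19 members, 15 of them higher, at percentile 32.5, the cells of cluster 1 differing in detected genes between the chips as given above. Cdkn1a was detected there in 11 of 27 wild-type cells and 12 of 25 labelled knockout, and Bbc3 in 4 of 27 and 7 of 25. Ccng1 went the other way, with 7 of 27 and 5 of 25. Cdkn1a was in 1 of 14 and 3 of 13 cells of cluster 1, and in 10 of 13 and 9 of 12 of cluster 3. Bbc3 was in 1 of 14 and 4 of 13 cells of cluster 1, and in 3 of 13 and 3 of 12 of cluster 3. Among club-like cells Cdkn1a was detected in 20 of 39 wild-type cells (51.3%, exact interval 34.8% to 67.6%) and in 7 of 36 labelled knockout (19.4%, 8.19% to 36.02%). Phlda3 was detected in 7 of 39 and 0 of 36, and Psrc1 in 8 of 39 and 1 of 36. These class values mix clusters of different size on the chips: Cdkn1a was in 15 of 22 and 1 of 10 cells of cluster 5, but in 4 of 15 and 3 of 19 cells of cluster 4. Psrc1 was in 7 of 22 and 0 of 10 cells of cluster 5, and in 1 of 15 and 1 of 19 cells of cluster 4. Mdm2, the p53 target that degrades p53, was in 8 of 39 and 12 of 36 club-like cells, with an interval of the difference from -7.12 to 31.8 percentage points, while its mean TPM there was 66.5 in wild type and 8.50 in cells labelled knockout. Btg2, an antiproliferative target, was higher over all cells, with means of 4.57 ± 3.85 and 6.28 ± 3.15.

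**Figure D4:**
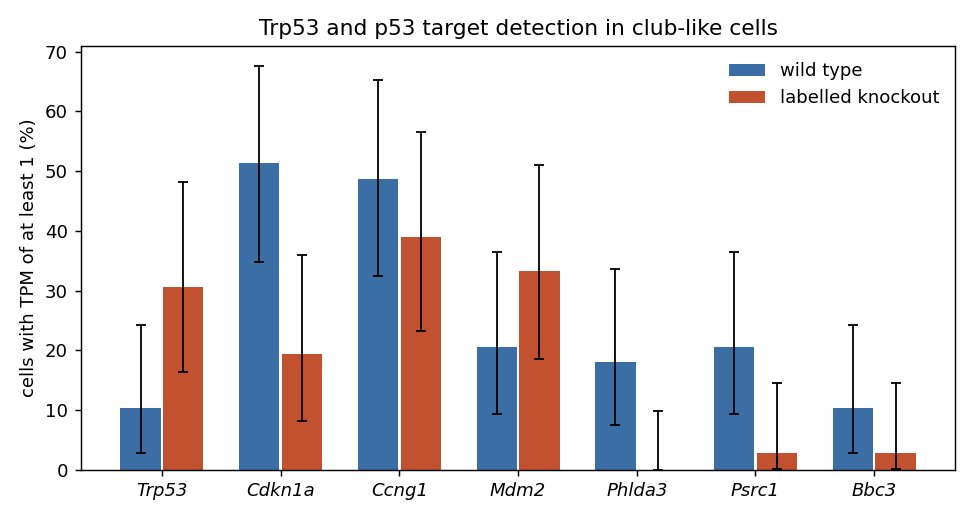
Percent of club-like cells with a TPM of at least 1 for Trp53 and 6 p53 target genes; bars are 39 wild-type cells and 36 cells labelled knockout, and error bars exact 95% binomial intervals, which cover counting error only. Cdkn1a is detected in 51.3% and 19.4% of cells, while Trp53 is detected in 10.3% and 30.6%.

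Among the cell cycle genes, those of DNA replication stood high against matched genes over all cells. The G1/S list had a median difference of 0.45 over 22 members, 21 of them higher, at percentile 99.6 of matched lists. Pcna, the replication clamp, was detected in 33.3% of wild-type cells and 57.4% of cells labelled knockout, and Gmnn in 27.3% and 49.2%. In alveolar-type-2-like cells this list was at percentile 54.6. The G2/M list had a median of 0.22, at percentile 41.8, which was 96.7 in cells with at least 2000 genes and 99.8 by ratio of mean TPM. With pseudocounts of 0.1 and 10 the percentile was 20.9 and 86.7, and without spike-ins it was 28.2. Cells with at least 5 of 16 mitotic genes numbered 0 of 66 in wild type, which allows a share of up to 4.55%, and 3 of 61 labelled knockout (4.92%, 1.03% to 13.7%). The interval of that difference, -1.46 to 13.5 percentage points, spans 0, and 5 and 6 cells lay near the bound, with 3 to 6 of these genes. With any TPM above 0 counted, they numbered 4 of 66 (6.06%) and 11 of 61 (18.03%), a difference of 11.97 percentage points with an interval from 0.53 to 23.99. At a TPM of at least 5 they numbered 0 of 66 and 2 of 61, with an interval of the difference from -2.71 to 11.19. More genes were detected per cell on the chip labelled knockout, and these counts were not corrected for that.

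Of the cell type lists, club cell genes had a median difference of 1.04 (35 of 36 members higher, percentile 99.6) and goblet cell genes a median of 0.89 (9 of 10 members higher, percentile 100). The club median was 0.58 in cells with at least 2000 genes (percentile 99.5) and 0.38 by ratio of mean TPM (percentile 97.4). With each cell centred 21 of 36 club and 5 of 10 goblet members were above 0, at unmoved percentiles. The mix of clusters, which differed between the chips, was not separated from the level per cell in these lists. The 5 ciliated genes detected over all cells had a median of 0.49, at percentile 97.0. In club-like cells 12 members were detected, at percentile 85.0, and in alveolar-type-2-like cells 4 members, at percentile 79.4. Over all cells the median was 0.23 to 0.85 by pseudocount and 2.17 by ratio of mean TPM. Of these 5 ciliated genes 4 were higher and 1 lower over all cells. Tppp3 was detected in 13.6% and 32.8% of cells, and 1110004E09Rik in 21.2% and 14.8%. The Tppp3 difference was 2.47 in alveolar-type-2-like cells and 0.55 in club-like cells. Alveolar type 2 genes stood at percentile 75.5 and MHC class II genes at percentile 64.4, while both lists were lower in the bulk knockout by camera (adjusted p = 0.668 for each with an estimated correlation). Oxidative phosphorylation genes were at percentile 99.4 over all cells, 89.1 in club-like cells and 100 in alveolar-type-2-like cells. Ribosomal protein genes, 33 of 35 of which were higher over all cells, were at percentile 0.6 there, 0.0 in club-like cells (15 of 35 higher) and 69.3 in alveolar-type-2-like cells.

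The 2 data sets were compared through the 50 bulk genes with the smallest p in each direction, since fewer than 20 were called. Of those higher in bulk, 28 were detected in the cells, with a median difference of 0.35, at percentile 97.0 of matched lists, and 22 of 28 (78.6%) were higher in cells labelled knockout, against 76.1% of all genes compared. By ratio of mean TPM these genes stood at percentile 48.9. Of those lower in bulk, 28 were detected, with a median of 0.18, at percentile 45.1, and 12 of 28 (42.9%) were lower, against 23.9% of all genes compared. With 200 genes in each direction the medians were both 0.24, at percentiles 76.3 and 70.4. Of those higher in bulk 77 of 102 (75.5%) were then higher in cells labelled knockout, and of those lower in bulk 32 of 112 (28.6%) were lower.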

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

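No test was added here after the values were seen; the gene lists were fixed beforehand. The off-chip positive control of the knockout chip, a sample that no comparison used, held transcripts of 2 lists of which few members were detected in the captured cells. Of 47 ciliated genes, 22 were at a TPM of at least 1, against 0 in the negative control, and 3 of these 47 were found in at least 10% of the kept cells. Of 21 immune genes, 12 were at a TPM of at least 1, against 0 in the negative control. The positive control held 7953 genes at this level, against medians of 3130.5 in wild-type cells and 3580 in cells labelled knockout. Detection in 1 sample and in a share of single cells are unlike measures, so these counts do not show cell types lost at capture. The summed TPM was 230 for the ciliated list and 175 for the immune list, beside 608118 for the club list. The negative control held 2 genes at a TPM of at least 1 other than spike-ins, Scgb1a1 at 3.72 and Sftpc at 3.22. No biological explanation was tested, and the control is a single sample.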

How the results depend on the processing

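The alternatives without spike-ins and with alveolar-type-2-like clusters alone were chosen only after the data were seen. No paired analysis was possible because the bulk genotypes share no replicate number and the numbers of the single cells only name wells. The cause was not tested for any change below unless a smaller set of libraries or genes is its construction. FPKM and TPM leave the depth unknown.

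In bulk, an estimated correlation and fry each gave 0 lists past; the p53 target list was at adjusted p = 0.400 and 0.118 and the ciliated list at 0.668 and 0.352 (limma). Called genes numbered 2 with a pseudocount of 0.1, 913 with library weights, and 1 to 408 leaving out 1 library, the highest without wild-type replicate 1. Lists past numbered 11 with no filter and 6 to 11 leaving out 1 library. The G2/M list was at adjusted p = 0.00885 with no filter, 0.936 in the other direction at an FPKM of at least 5, and 0.0167 to 0.817 leaving out 1 library. The G1/S list turned direction with library weights (0.798) and ranged from 0.131 to 0.950 leaving out 1 library. The club list turned direction with library weights (0.0754) and ranged from 0.00669 to 0.739. The bulk Trp53 log2 fold change was -1.22 with library weights, past the threshold, and -1.25 to -1.03 leaving out 1 library.

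In single cells, genes differing by size numbered 26 in cells with at least 2000 genes, 93 in club-like cells, 242 in alveolar-type-2-like cells, 314 and 6 with pseudocounts of 0.1 and 10, 86 by ratio of mean TPM and 12 with each cell centred. The p53 target median was 0.088 with no minimum of genes, -0.10 with at least 2000 genes, -0.20 in club-like cells, 0.23 in alveolar-type-2-like cells, -0.43 by ratio and -0.81 centred. The G1/S median was 0.61 in club-like cells, 0.79 and 0.16 with pseudocounts of 0.1 and 10, 1.35 by ratio and -0.36 centred. The G2/M median was 0.34 with a pseudocount of 0.1, 0.91 by ratio and -0.60 centred. The club median was 1.24 with no minimum, 0.58 with at least 2000 genes, 0.77 in club-like cells, 1.21 and 0.55 with the pseudocounts, 0.38 by ratio, 0.22 centred and 0.86 without spike-ins. The ciliated median was 0.24 over 12 members in club-like cells, 0.85 and 0.23 with the pseudocounts, 2.17 by ratio and -0.33 centred. Resolution 0.5 gave 3 clusters, and with 200 bulk genes per direction the difference between the medians was -0.001.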

Other observations

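The tests on cell share and Trp53 detection against like genes, and on clock genes not yet seen, had their outcomes set before the values were seen; all other tests here, and the test of Trp53 at any TPM above 0, were chosen after.

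Of 14 circadian clock genes, 13 had a bulk fold change in the direction of a shift in phase, and none passed the limma adjusted threshold. Cry1, Npas2 and Arntl, which peak together, had negative fold changes, Arntl being at 28.5 ± 5.18 FPKM in wild type and 13.5 ± 2.17 FPKM in knockout (SD, n = 3 each). Nr1d2, Nr1d1, Per2, Per3, Dbp and Ciart, which peak at another phase, had positive fold changes; Per2 was at 5.83 ± 1.42 FPKM and 10.5 ± 1.05 FPKM. Of the 8 clock genes whose values had not been seen when the outcome was set, 7 did not overlap between the genotypes, against 10% by chance and 19.3% of all tested genes; the exception was Clock. These genes regulate each other and are not independent. The clock genes were listed after the first of them had been seen, and no set test was run on them.

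Tissue taken at different times of day is a candidate explanation of the clock pattern. Of 8 clock genes whose values had not been seen when the outcome was set, 87.5% lay in the phase direction, as this explanation needs. The labels used here give no time of collection. A different mix of cell types stays open: the clock score (late minus early genes, mean log2) of wild-type replicate 1, whose ciliated level lies with the knockout libraries, was -0.57 relative to the other wild-type libraries, away from knockout, but 1 library decides nothing. An effect of p53 on the clock was not tested and also stays open.

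For the higher ciliated genes in bulk knockout, a candidate is a lower share of club cells with the other types in unchanged proportion. That would raise the genes of every other type, yet the alveolar type 2 list had a median log2 fold change of -0.98. Its level was lower in each knockout library than in each wild-type library. Without wild-type replicate 1 the alveolar type 2 median was -0.46, still below 0, where this explanation needs a rise. That was short of the bound of -0.5 set for this test. A lower share of both club and alveolar type 2 cells would lower this list too, so the test cannot decide on that. The club cell list had a median of 0.19 over all libraries, but was lower in knockout without wild-type replicate 1, as given above. Scaling by a few abundant genes would move all genes, and their median log2 fold change was 0.008. A larger share of ciliated cells in the knockout libraries may account for it: of 98 tested genes with a cilium name prefix outside the list, 77.6% were higher, with a median log2 fold change of 0.45, against 51.4% of all tested genes; this lay between the bounds set beforehand, so the test did not decide. More ciliated cells and more transcript per cell cannot be told apart in bulk, and an effect of p53 on ciliated differentiation stays open as untested. Wild-type replicate 1 also had the ciliated level of the knockout libraries.

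For the higher detection of Trp53 in cells labelled knockout, more genes per cell on that chip stay open. At a TPM of at least 1 the difference lay at percentile 99.2 among 1171 genes detected within 2 percentage points of the same share of all cells, past the bound set against this explanation, but at any TPM above 0 it lay at percentile 83 among 860 genes, so the test turned on the detection limit. Exchanged chip labels could give it, and then p53 targets would stand high in cells labelled knockout. They stood at percentile 0.4, and at 2.6 with remarked wells included. With 1 chip per genotype the spread between chips is unknown, so an exchange cannot be told apart from a difference between chips. Reads from exons outside the deleted part stay open as untested, since the values are per gene.

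The real split of the 6 bulk libraries gave 1 called gene and the highest of the other splits 2; 5 of the 10 splits gave at least 1. With 10 splits no share under 0.05 can be reached.

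In bulk, Ddx3y, a gene of the Y chromosome, was present in knockout replicate 10 and the Xist level there was low, so the libraries were not all of 1 sex. Rps27, a ribosomal protein gene, was at 229 ± 85.1 FPKM in wild type and 29.2 ± 35.6 FPKM in knockout (SD, n = 3 each) with a limma adjusted p of 0.308.

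In the cells, median gene counts were higher on the chip labelled knockout within both classes, 3864.5 against 3225 among club-like cells and 3127 against 2529 among alveolar-type-2-like cells. Median ERCC species above 0 were 30 and 33.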
